A study of Macaca mulatta with 14 samples.

How the data were processed

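The samples were peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes isolated from blood) of 14 male rhesus macaques. The labels put 7 animals on a control diet and 7 on calorie restriction (CR), and their titles call the samples of a group biological replicates. Per the labels, total RNA was extracted with Trizol and made into biotin-labelled cRNA for an Affymetrix expression array, with 1 array per animal. The age of each animal was not used, because the design text gives ages only as a range for each group (24 to 27 years for controls and 24 to 30 years for CR animals), so age was no covariate. The same text gives 16 years of CR in a sentence that names both groups, and reading this as the CR animals' time on the diet is an assumption.

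The deposited values are MAS5 signal intensities on a linear scale, 1 value per probe set and array, and MAS5 is named in the submitters' processing notes without a version. MAS5 summarises the probes of a set into 1 signal and scales each array as a whole. In the deposited intensities, the mean without the highest and lowest values of each array was 500.0 on all 14 arrays, so total brightness was already equalised and a change in the total amount of RNA per cell would not be visible. The probe set definition and any filter used by the authors are not given in the sources used here, and detection calls were not used here. No scan date or other batch was given in the labels or the table.

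The table held 52865 probe sets. Intensities under 16 were set to 16, because MAS5 differences between very dim values carry mostly noise, and log2 was taken. After leaving out 99 AFFX control probe sets, the 50% of probe sets with the higher mean log2 over the 14 arrays were tested, which left 26383 with a geometric mean signal of at least 87.7. In the platform annotation, 24969 probe sets carried 1 gene symbol, 361 carried several and 27535 had no gene listed. Among the tested probe sets these numbers were 14925, 242 and 11216. The Entrez ID of 24629 single-gene probe sets was found in a current rhesus gene table, and 0 symbols differed. Genes were named only from probe sets with 1 symbol, and a gene was represented by its brightest tested probe set, which gave 9355 genes. Genome positions were not used here, since the annotation names no build for the probe sets.

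Each probe set was tested for CR minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, no covariate), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Differences are on the log2 scale of MAS5 signal, with the standard error (SE) of the moderated fit. These choices, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where an added test is named.

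A total of 36 gene lists from general knowledge of blood cell types and of pathways discussed for calorie restriction were fixed, and 35 had at least 5 measured genes. The erythroid list had fewer and was not tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether the genes of a list differ from the other genes. The same test with a correlation estimated for each list, and fry, were run beside it. The fry test asks whether a list's genes move on balance in 1 direction, its mixed form whether they change in either direction, and neither compares a list with other genes. Adjustment was over the 35 lists. Some genes stand in several lists: 1 of the 18 measured NK and cytotoxic genes, 3 of the 12 monocyte genes, 3 of the 14 immediate early genes and 1 of the 18 inflammatory genes were also in another list. Of the 10 cell type marker lists, 9 were also scored per array, as the mean of log2 values after centring each gene on its mean over the 14 arrays. The scores of the diets were compared by a two-sided exact permutation test over all 3432 splits of the 14 arrays into 7 and 7, which cannot give a p under 0.000583.

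Named genes were chosen by a fixed rule. It takes up to 12 genes past the threshold in each direction, or the 8 with the smallest unadjusted p where none pass, then the 4 members of each called list with the smallest p in its direction and 2 members of each other list, and 22 genes fixed whatever their result. Values are also given for NKG7, CCL5, GZMA, NCAM1, KLRF1, CD14, FOS and RGS1, members of called lists outside this rule. They are not part of the counts of named genes below. RNA quality was measured as the log2 ratio of 3-prime to 5-prime control probe sets for GAPDH, ACTB and EF1A. The initial plan named GAPDH and ACTB, and EF1A was added to it. The covariate tests of RNA quality used GAPDH and EF1A. ACTB was not among them, and its 5-prime signal lay under the floor on 1 array. Depth does not apply to arrays, and their number limits the precision: the median SE of a difference was 0.25.

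The probe set test was tested on simulated arrays drawn from the means and residual SDs of the 26383 probe sets. It called 46 of 100 probe sets changed by 1 log2 unit, 92 of 100 changed by 2 log2 units and 8 unchanged probe sets, and with no change it called 0. The 200 changes were planted together in independent probe sets. With fewer true changes the adjusted threshold is stricter, so these shares do not give the share recovered then. Over 20 simulated sets of independent genes, camera called 0 of 700 unshifted lists, a rise of 0.5 in the NK list in 20 and a fall of 0.5 in the monocyte list in 14. On the real arrays genes of a list were correlated (estimated at 0.37 in the monocyte list). The simulated sets left this out, so their counts do not give the rate of false or missed list calls in these data. Alternatives covered quantile normalization, median centring, no floor or a floor of 64, no filter or the upper 25% by mean, the variance model, array weights, a surrogate variable, the replicate number as a block, each array left out in turn, the probe set that stands for a gene, and cell type scores as covariates. A fit without control 1 and CR 2, the array of each diet with the lowest mean correlation with the others, was added after seeing the data.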

Results

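The study asked how long-term calorie restriction relates to gene expression in PBMC of aged rhesus macaques. The design text gives 16 years of CR, read here as the time of the CR animals on the restricted diet. In all, 7 CR animals were compared with 7 on a control diet, all male. Each animal contributed 1 array. Arrays of the control group correlated with each other at a median r of 0.932 over the tested probe sets, arrays of the CR group at 0.919, and arrays of different diets at 0.919. In the deposited intensities, before any floor, no pair of arrays had the same value at more than 1 probe set.

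At the level of single genes, no probe set separated the diets after correction for the number tested. Among gene lists, cytotoxic lymphocyte genes had higher signal in CR animals, with GZMB (granzyme B, a protease of cytotoxic granules), CST7 and FGFBP2 passing over their list alone. Adjustment over 1 list does not account for the number of lists, and over all probe sets each had an adjusted p of 0.918 (limma). Monocyte markers, with a larger mean difference, immediate early genes and inflammatory cytokine genes were on the lower side, and genes of oxidative phosphorylation and the cytosolic ribosome on the higher side, with differences of well under 1 log2 unit for most members. These list calls used a preset correlation between genes, and 0 of them held when the correlation was estimated from the arrays.

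Of 26383 probe sets, 0 were higher and 0 were lower in CR at an adjusted p under 0.05 (limma), and the smallest adjusted p was 0.771. Over the alternatives the smallest adjusted p ran from 0.085 (without control 6) to 0.994 (without CR 3). At an unadjusted p under 0.05, limma gave 605 higher and 745 lower, 1350 in all, against 1319 that chance alone would give. A linear model per probe set without variance moderation gave 0 at adjusted p and 1341 at unadjusted p. After centring each array on its median, the unadjusted split was 901 higher and 548 lower. The median log2 difference over all tested probe sets was -0.012, and 235 probe sets differed by more than 1 log2 unit.

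The genes with the smallest unadjusted p on the higher side were ASL (argininosuccinate lyase of the urea cycle), OAT (ornithine aminotransferase), UCKL1, LOC699418, TUBGCP6 (a gamma-tubulin complex component), PANX2, JAKMIP1 and CCDC180. ASL was at 9.65 ± 0.15 (log2 signal, SD, n = 7) in controls and 10.31 ± 0.23 in CR, a difference of 0.67 ± 0.15 (SE), and all 7 CR values lay above the control median. For OAT the difference was 1.27 ± 0.29, with 6 of 7 CR values above the control median, and for UCKL1 0.73 ± 0.17, with 7 of 7. All 3 had an adjusted p of 0.771 (limma), so none passed. On the lower side the rule named MED1 (a subunit of the Mediator complex), FAM135A, LACTB, TUT1, AMER1, PKMYT1 (a kinase that restrains CDK1), UBASH3B and LOC696048. MED1 differed by -0.60 ± 0.15, FAM135A by -0.83 ± 0.21 and PKMYT1 by -1.24 ± 0.33, with 0 of 7 CR values above the control median in each, and none passed (adjusted p 0.869, 0.869 and 0.918, limma). Of the other 3 probe sets of MED1, 1 had the opposite sign (0.023 ± 0.31).

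Cytotoxic lymphocyte genes stood on the higher side in CR. In the list of NK and cytotoxic T cell markers, 14 of 18 measured genes were higher in CR, with a median difference of 0.26 and a mean of 0.32, and camera called the list (adjusted p = 0.0046, and adjusted p = 0.482 with an estimated correlation). Adjusted over the list alone, 3 genes passed, and over all probe sets 0 did. These were GZMB, CST7 (cystatin F, an inhibitor of lysosomal cathepsins) and FGFBP2 (a secreted protein of cytotoxic lymphocytes). GZMB rose from 15.34 ± 0.47 (log2 signal, SD, n = 7) to 16.05 ± 0.38, a 1.63-fold difference, CST7 from 11.98 ± 0.95 to 13.14 ± 0.50, a 2.23-fold difference, and FGFBP2 by 1.16 ± 0.36 (SE) from 10.84 ± 0.98 in controls. Each had an adjusted p of 0.0271 over the list alone and 0.918 over all probe sets (limma), with 7 of 7 CR values above the control median. GZMH (0.69 ± 0.25), NKG7 (0.48 ± 0.22) and CCL5 (0.74 ± 0.36) were higher without passing, and GZMA was lower (-0.57 ± 0.33). NCAM1 differed by -0.065 ± 0.17 and KLRF1 by 0.010 ± 0.40. Without CR 7 the camera call of this list ended (mean 0.27, adjusted p = 0.0536). The NK score was highest in CR 7 (0.45) and CR 6 (0.43), the arrays lowest for monocyte markers.

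Among T cell markers, 6 of 8 measured genes were higher (median 0.30, mean 0.30), camera called the list higher (adjusted p = 0.0344, and adjusted p = 0.55 with an estimated correlation), and 0 genes passed adjusted over the list alone. The call ended without control 4 (0.26), control 5 (0.22), control 6 (0.28), CR 2 (0.24), CR 6 (0.26) or CR 7 (0.29), in the upper 25% by mean (0.27) and with array weights (0.26). CD5, a surface regulator of T cell receptor signalling, differed by 0.69 ± 0.24 (another probe set gave 0.19 ± 0.22), UBASH3A by 0.80 ± 0.30, SIT1 by 0.50 ± 0.23 and SH2D1A by 0.27 ± 0.21. Markers of naive and memory T cells were not called, with 3 of 7 higher and a mean of -0.08 (adjusted p = 0.604). No test compared them with the T cell list. TCF7, a transcription factor of naive and memory T cells, was at -0.37 ± 0.18, though another probe set of the gene gave 0.080 ± 0.23, and MAL was at -0.60 ± 0.45. B cell markers were higher in 8 of 9 genes with a mean of 0.16 (adjusted p = 0.337), among them CD79B (0.30 ± 0.19). With 1 array left out the mean of the B cell list ran from 0.081 to 0.25. The plasma cell list had a mean of -0.038 (adjusted p = 0.677), with JCHAIN at -0.61 ± 0.38.

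Myeloid genes stood on the lower side. All 12 measured monocyte markers were lower in CR, with a median difference of -0.47 and a mean of -0.54, and camera called the list (adjusted p = 0.00171, and adjusted p = 0.55 with an estimated correlation), while 0 genes passed adjusted over the list alone or over all probe sets. VCAN (versican) differed by -1.07 ± 0.52 and FCN1 (ficolin 1) by -1.24 ± 0.60, which are 0.475-fold and 0.424-fold, CD68 by -0.53 ± 0.31, TLR2 by -0.61 ± 0.44 and CD14, the monocyte surface receptor, by -0.36 ± 0.70. The spread was uneven: the monocyte score was -1.51 in CR 6 and -1.21 in CR 7 but 0.78 in CR 1 and 0.49 in CR 5, and -0.76 in control 1. With 1 array left out the list mean ran from -0.72 (without CR 1) to -0.34 (without CR 6), and the list was called each time. No fit left out CR 6 and CR 7 together, so these fits do not show whether the call rests on that pair of arrays. The platelet score moved with it among CR arrays (r = 0.902, n = 7), at -1.99 in CR 6, -1.19 in CR 7, 1.21 in CR 1 and 0.96 in CR 5, but not among control arrays (r = 0.036, n = 7). Neutrophil markers were lower in 8 of 9 (mean -0.38, adjusted p = 0.0344, and adjusted p = 0.55 with an estimated correlation), with S100A8 at -0.99 ± 0.61, S100A9 at -1.02 ± 0.74, MPO at -0.45 ± 0.25 (another probe set gave 0.16 ± 0.50) and CSF3R at -0.46 ± 0.33, and 0 passed adjusted over the list alone. Their score was -1.40 in CR 7 and -1.05 in CR 6, the arrays that were also lowest for monocyte markers, and without CR 7 the mean was -0.17 (adjusted p = 0.212). PBMC are isolated as lymphocytes and monocytes, so this list is no measure of neutrophil number. Whether its signal came from neutrophils or monocytes was not tested.

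Immediate early genes, which are induced within minutes of cell stimulation, were lower in 13 of 14 measured genes (median -0.31, mean -0.36, adjusted p = 0.000619, and adjusted p = 0.385 with an estimated correlation). EGR2 fell by 0.98 ± 0.29, with 1 of 7 CR values above the control median, and was the only member to pass adjusted over the list alone (adjusted p = 0.0498, limma). Over all probe sets 0 passed. IER2 was at -0.58 ± 0.21, NR4A1 at -0.79 ± 0.29, DUSP5 at -0.73 ± 0.42 and FOS at -0.21 ± 0.37, and RGS1 was higher (0.31 ± 0.49). The score of this list was lowest in CR 7 (-0.81) and CR 6 (-0.52), where the monocyte score was lowest too. Of 18 inflammatory cytokine and NF-kB target genes 13 were lower (median -0.15, mean -0.27, adjusted p = 0.0344, and adjusted p = 0.81 with an estimated correlation), with 0 passing adjusted over the list alone. IL1RN, the interleukin-1 receptor antagonist, was at -0.58 ± 0.25, CCL3 at -0.76 ± 0.43, NLRP3 at -0.82 ± 0.55 and IL1B at -0.64 ± 0.44. The score of these genes was -1.14 in CR 6 and -0.82 in CR 7. The list mean was -0.11 without CR 6 (adjusted p = 0.291) and -0.16 without CR 7 (adjusted p = 0.228).

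**Figure D1:**
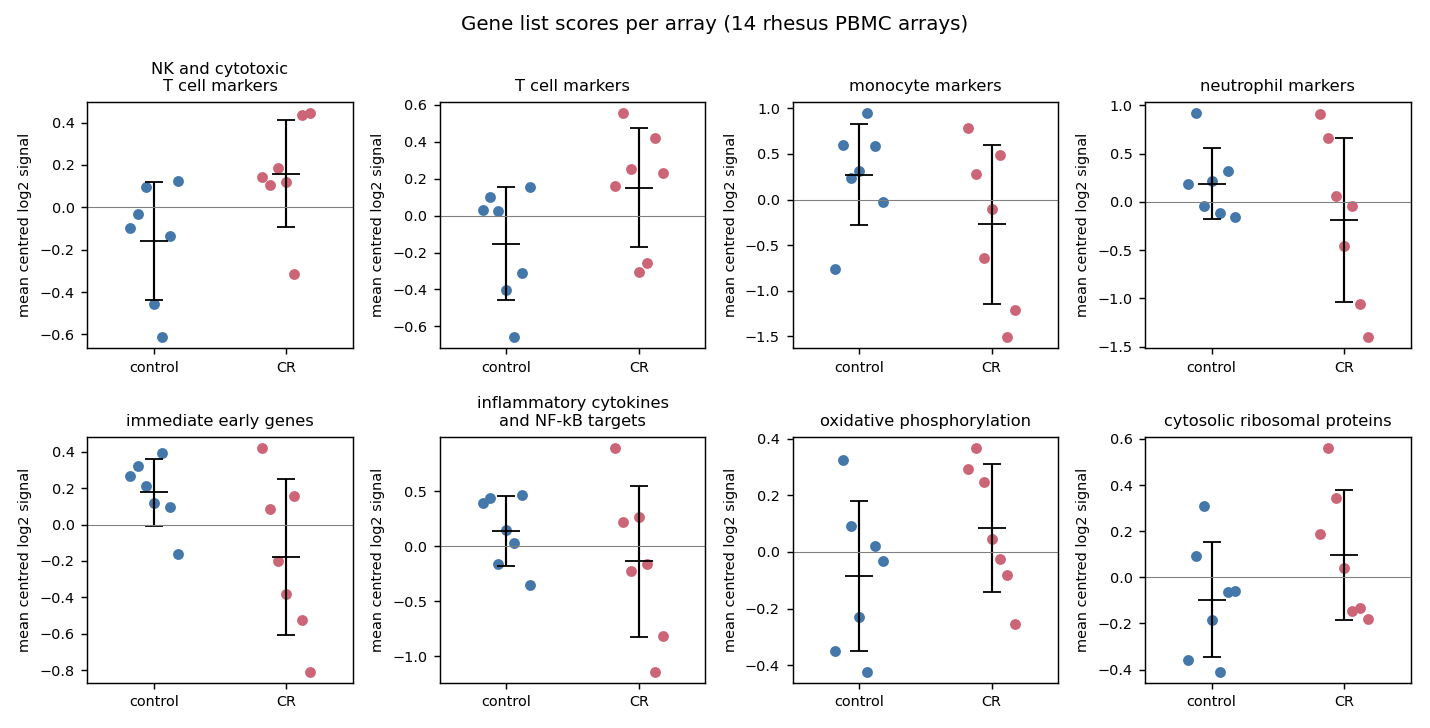
Scores of 8 gene lists on each of the 14 arrays, as the mean over the list of log2 signal centred per gene on its mean over all arrays (vertical axis, log2 units), with control animals in blue, CR animals in red, and the mean and SD of each diet in black. In the NK and cytotoxic list 6 of 7 CR arrays lie above the control median, and in the monocyte list CR 6 and CR 7 lie at -1.51 and -1.21.

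Genes of oxidative phosphorylation, the mitochondrial respiratory chain, were higher in 44 of 51 (median 0.14, mean 0.17, adjusted p = 0.002, and adjusted p = 0.81 with an estimated correlation), and 0 passed adjusted over the list alone. NDUFB4 of complex I differed by 0.57 ± 0.21 (another probe set gave 0.0088 ± 0.29), COX6B1 of complex IV by 0.40 ± 0.15, ATP5F1E of ATP synthase by 0.66 ± 0.26 and UQCRC1 of complex III by 0.48 ± 0.20. The 2 other probe sets of UQCRC1 gave 0.34 ± 0.27 and -0.094 ± 0.16. Cytosolic ribosomal protein genes were higher in 27 of 34 (median 0.13, mean 0.19, adjusted p = 0.015, and adjusted p = 0.81 with an estimated correlation), with 0 passing adjusted over the list alone. RPS18 was at 0.44 ± 0.16, RPL5 at 0.75 ± 0.34, RPL29 at 0.77 ± 0.30 and RPL15 at 0.37 ± 0.17. The RPL5 probe set was dim, at a mean log2 signal of 6.53 in controls and 7.28 in CR. That is close to the lowest mean tested (6.45), against 13.94 for RPL29 in controls. The 2 other probe sets of RPL29 gave 0.12 ± 0.26 and -0.19 ± 0.19, and the other of RPL15 gave -0.27 ± 0.23. Control 1, which correlated least with the other arrays, and control 5 had the lowest oxidative phosphorylation scores (-0.35 and -0.42) and the lowest ribosomal scores (-0.36 and -0.41). Without control 1 and CR 2 the mean of the oxidative phosphorylation list was 0.080 (adjusted p = 0.202) and that of the ribosomal list 0.072 (adjusted p = 0.504). Quantile normalization also ended the ribosomal call (mean 0.096, adjusted p = 0.927). Mitochondrial ribosomal proteins were higher in 41 of 58 genes without a call (mean 0.12, adjusted p = 0.0528), among them MRPL41 (0.81 ± 0.26). With 1 array left out the mean ran from 0.077 to 0.18, and the list was called without control 2, 3, 6 or 7 or CR 4, 5, 6 or 7, and with quantile normalization, median centring and the mean of a gene's probe sets.

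Insulin, IGF and FOXO signalling genes were lower in 16 of 24 (median -0.18, mean -0.14, adjusted p = 0.0367, and adjusted p = 0.385 with an estimated correlation), and 0 passed adjusted over the list alone. The p53 and FOXO target SESN1 was at -0.37 ± 0.16, BCL6 at -0.46 ± 0.24, the phosphoinositide 3-kinase subunits PIK3R1 and PIK3CB at -0.49 ± 0.27 and -0.48 ± 0.30. FOXO1 itself was at 0.46 ± 0.21. Splicing factor genes were lower in 11 of 16 (median -0.13, mean -0.08, adjusted p = 0.0344, and adjusted p = 0.385 with an estimated correlation), with 0 passing adjusted over the list alone. HNRNPU was at -0.42 ± 0.15, SRSF5 at -0.35 ± 0.13 (3 others gave -0.54 ± 0.25, -0.34 ± 0.25 and -0.066 ± 0.19), HNRNPA1 at -0.32 ± 0.19 and HNRNPK at -0.18 ± 0.12. The 3 other probe sets of HNRNPK gave -0.31 ± 0.32, 0.15 ± 0.34 and 0.094 ± 0.26. The splicing call ended without control 5 (mean -0.060, adjusted p = 0.12) or CR 7 (-0.082, adjusted p = 0.0539). The insulin list lost its call without any of 6 arrays in turn (control 2, 4 or 5, CR 2, 6 or 7), and its mean was -0.099 without CR 7 (adjusted p = 0.162). With the T cell, B cell, monocyte and NK scores as covariates, 0 of the 6 called lists that are not cell type markers were called. The mean of the insulin list was then -0.00017 (adjusted p = 0.861), that of the splicing list -0.075 (adjusted p = 0.223) and that of the oxidative phosphorylation list 0.079 (adjusted p = 0.064).

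Of the 35 lists, camera called 4 higher and 6 lower, and fry called 0. At least 10 lists were called in 19 of 100 splits of the arrays into 7 and 7, the diet split included. The other 25 lists were not called. In the cholesterol synthesis list (mean -0.10, adjusted p = 0.185), INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.78 ± 0.22 and passed adjusted over the list alone (adjusted p = 0.036, limma) but not over all probe sets (adjusted p = 0.918), with 0 of 7 CR values above the control median. Its other probe set gave -0.36 ± 0.30. The dendritic cell list (mean -0.063, adjusted p = 0.677) held 1 gene passing adjusted over the list alone, GZMB again. Interferon response genes were lower in 18 of 25 (mean -0.12, adjusted p = 0.0802), and with 1 array left out the mean ran from -0.23 to -0.029. The list was called without control 1 (-0.23), control 6 (-0.14), CR 1 (-0.17) or CR 6 (-0.18), with array weights (-0.22) and with the mean of a gene's probe sets (-0.14). Its members were mixed, with IFI44 at -0.66 ± 0.31 and IRF7 at 0.57 ± 0.24. Another probe set of IRF7 gave -0.0010 ± 0.21. The means and camera adjusted p of lists on the higher side were 0.031 for MHC class II (0.677), 0.086 for the tricarboxylic acid cycle (0.677), 0.055 for fatty acid oxidation (0.604), 0.058 for glycolysis (0.635), 0.079 for the proteasome (0.677), 0.0062 for autophagy and lysosome (0.808), 0.059 for mTOR signalling (0.635) and 0.081 for the cell cycle (0.272). On the lower side they were -0.11 for platelet markers (0.604), -0.059 for heat shock genes and chaperones (0.238), -0.057 for the unfolded protein response (0.449), -0.12 for the glucocorticoid response (0.315), -0.086 for DNA damage and senescence (0.245), -0.10 for toll-like receptor signalling (0.261) and -0.22 for complement and coagulation receptors (0.124). For antioxidant and NRF2 targets the median was 0.016 and the mean -0.0034, and for sirtuins, AMPK and mitochondrial biogenesis the median was 0.092 and the mean -0.013. For both, camera gave the direction as lower and fry as higher (camera adjusted p = 0.971 each). The circadian clock list had a mean of -0.018 and was lower by camera (adjusted p = 0.971) and higher by fry.

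**Figure D2:**
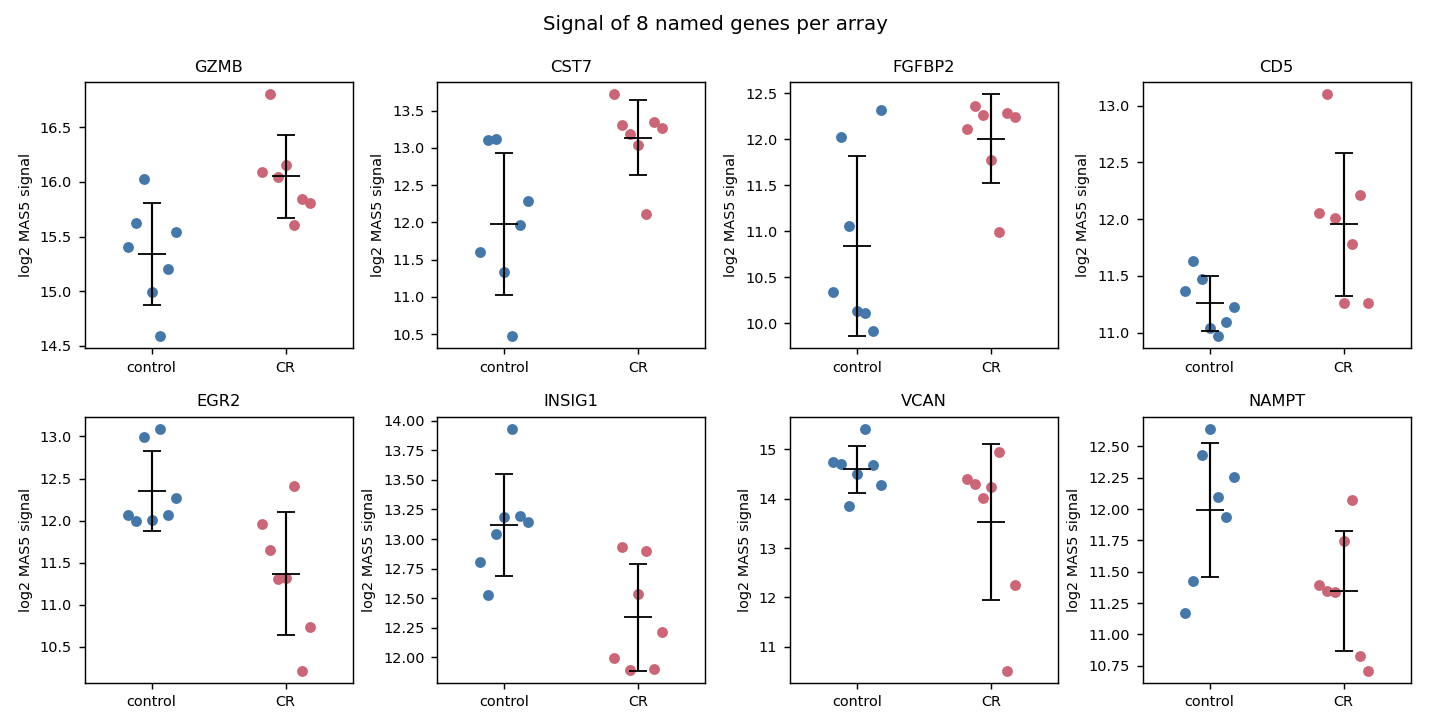
Log2 MAS5 signal (vertical axis) of 8 named genes on each array, control animals in blue and CR animals in red, with the mean and SD of each diet in black. GZMB, CST7, FGFBP2, EGR2 and INSIG1 passed adjusted over their lists alone, and 0 of the 8 passed over all probe sets.

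Of the 22 genes fixed whatever their result, 16 were tested and 0 passed. PPARGC1A, PDK4 and TNF were on the array below the signal filter, and FOXO3, HMOX1 and HSPA1A had no single-gene probe set in the annotation used. NAMPT, the enzyme of the NAD salvage pathway, was at -0.65 ± 0.25 with 0 of 7 CR values above the control median (adjusted p 0.918, limma). SIRT1 differed by 0.014 ± 0.19, CPT1A by 0.31 ± 0.23 (another probe set gave -0.65 ± 0.46), the glucocorticoid-induced genes FKBP5 and TSC22D3 by 0.29 ± 0.24 and -0.14 ± 0.18, IGF1R by -0.54 ± 0.48, IRS2 by -0.31 ± 0.29 (another probe set gave 0.38 ± 0.22) and TXNIP by -0.021 ± 0.13. Other probe sets of TXNIP gave -0.55 ± 0.28, -0.22 ± 0.26, -0.11 ± 0.28 and -0.032 ± 0.52. IL6 was at -0.58 ± 0.66 (another probe set gave 0.19 ± 0.56), CXCL8 at -0.35 ± 0.49, CDKN1A at -0.45 ± 0.31, CDKN2A at 0.17 ± 0.27, SOD2 at -0.52 ± 0.32 and CAT at 0.43 ± 0.37.

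When whole arrays were the unit, none of the 9 cell type scores differed between the diets after adjustment. The exact permutation test was also run, without being planned, on the scores of all 35 lists, and none passed (smallest adjusted p = 0.698). For the 6 called lists that are not cell type markers, exact p ran from 0.0594 (splicing) to 0.358 (inflammatory). It was 0.0676 for immediate early genes and 0.219 for oxidative phosphorylation. The NK and cytotoxic score was -0.16 ± 0.28 (SD, n = 7) in controls and 0.16 ± 0.25 in CR, a difference of 0.32 with 6 of 7 CR arrays above the control median (two-sided exact permutation p = 0.0443, adjusted p = 0.399 over 9 scores). The T cell score differed by 0.30 (exact p = 0.0997, adjusted 0.448). The monocyte score differed by -0.54, at 0.27 ± 0.55 against -0.27 ± 0.87 (exact p = 0.186, adjusted 0.559). The neutrophil, B cell, naive and memory T cell, platelet, dendritic cell and plasma cell scores differed by -0.38, 0.16, -0.081, -0.11, -0.063 and -0.038, with exact p from 0.306 to 0.862. Without CR 5, the NK score difference was 0.40 and passed (exact permutation, adjusted p = 0.0472). CR 5 had the lowest NK score of the CR arrays (-0.31), so leaving it out had to raise the difference. No cell type score passed with any other single array left out.

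RNA quality measures did not separate the diets in these tests. However, the 3-prime signal was far above the 5-prime signal on all 14 arrays, and a comparison of the diets does not judge a bias that all arrays share. The 3-prime control probe set of GAPDH was 33.5 to 181 times as bright as the 5-prime one, and that of EF1A 9.46 to 41.6 times, both highest in control 1. For ACTB the factor was 274 to 2240 except in CR 2, whose 5-prime ACTB signal of 9.77 lay below the floor. The ACTB ratio of CR 2 is therefore not exact, and the planned comparison of the diets on ACTB is not used here. The log2 ratios differed between the diets by 0.43 for GAPDH (exact permutation p = 0.222) and -0.044 for EF1A (exact permutation p = 0.882), and the median signal by 0.56 (exact permutation p = 0.949). The share of intensities under 16, in percent of an array, differed by 0.099 (exact permutation p = 0.939). The first 3 principal components held 18.3%, 14.8% and 12.4% of the variance, with exact permutation p for diet of 0.949, 0.873 and 0.0268, and 0.0804 for the third after adjustment over the 3.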

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

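No test in this part was chosen after a result was seen. In each diet, the gap between the most extreme array and its nearest neighbour was compared with the range of the 7 arrays for 158 quantities (named genes, list scores and quality measures), and 15 of the 316 tests passed Dixon's 95% critical value. Chance alone gives about 1 in 20 of independent tests, and the total is not above that. Many named genes are also members of the scored lists, so these tests are not independent. The total cannot show whether an array with several flags, such as control 1, stands apart by chance. Each flag is given only as a value.

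Control 1 was low in the mean correlation with the other arrays (0.878, against 0.912 to 0.929 for the other control arrays). It was also low in the unfolded protein response score (-0.42, against -0.022 to 0.21), in the autophagy and lysosome score (-0.38, against -0.010 to 0.21) and in JCHAIN (7.80, against 9.01 to 9.90 log2). It was high in PIK3R1 (13.90, against 11.99 to 12.72). CR 2 was high in the ACTB 3-prime to 5-prime log2 ratio (13.49, against 8.68 to 9.22) and in median signal (127.6, against 94.6 to 107.5). The ACTB ratio of CR 2 rests on a 5-prime signal of 9.77, below the floor of 16, so it is not an exact ratio. CR 5 was low in CST7 (12.11, against 13.04 to 13.72) and FGFBP2 (10.996, against 11.77 to 12.36). Both genes are members of the NK list, and leaving CR 5 out took the NK score past the threshold. Control 2 was high in S100A9 (13.96, against 10.73 to 11.84) and RFXANK (10.28, against 9.63 to 9.90). MAL was low in control 3 (4.71, against 7.39 to 8.35). BECN1 was high in CR 4 (13.54, against 13.16 to 13.25). C1QA was low in CR 6 (9.48, against 10.22 to 10.73). The naive and memory T cell score was high in CR 1 (0.60, against -0.32 to 0.049).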

How the results depend on the processing

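The fit without control 1 and CR 2 was chosen only after the results were seen, and the other alternatives were planned. The count of probe sets at adjusted p under 0.05 was 0 in all 27 alternatives, and 0 named genes passed in any (smallest adjusted p 0.397 over 3000 values). The count at unadjusted p under 0.05 was 1350. It ran from 917 (without control 5) to 1792 (without control 2) over the arrays left out in turn, and was 1881 with a surrogate variable, 1766 with array weights and 1598 without control 1 and CR 2. It was 2598 without the filter and 803 in the upper 25% by mean, where more and fewer probe sets were tested. Camera with robust variances was planned and not run, since camera has no such option.

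The replicate numbers gave no clear pairing of the samples, and a weak one is not excluded. The deviations of same-numbered arrays correlated from -0.11 to 0.18, 4 of 7 pairs were over 0.1, and 3 of 14 arrays correlated best with their own number in the other diet. With the replicate number as a block, 0 probe sets passed, 1735 had an unadjusted p under 0.05 and 9 lists were called. The neutrophil list (-0.38, adjusted p = 0.0634) and the splicing list (-0.085, adjusted p = 0.0558) were not called, and the mitochondrial ribosomal list was (0.12, adjusted p = 0.033). No other call changed with the block.

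Of the 10 called lists, 0 were called with an estimated correlation and 0 by fry, with the means as they were: 0.32 (NK and cytotoxic), 0.30 (T cell), 0.17 (oxidative phosphorylation), 0.19 (ribosomal), -0.54 (monocyte), -0.38 (neutrophil), -0.27 (inflammatory), -0.36 (immediate early), -0.14 (insulin) and -0.085 (splicing). With cell type scores as covariates 0 of 6 were called, at 0.079, 0.080, -0.063, -0.14, -0.00017 and -0.075 for the oxidative phosphorylation, ribosomal, inflammatory, immediate early, insulin and splicing lists (adjusted p from 0.064 to 0.861). That fit spends 4 more degrees of freedom. The count of called lists ran from 5 (without CR 7) to 12 (without control 7 or CR 1) over the arrays left out.

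The monocyte (-0.72 to -0.34), immediate early (-0.46 to -0.25) and oxidative phosphorylation (0.11 to 0.24) lists were called without any of the 14 arrays in turn. The monocyte and immediate early scores were lowest in CR 6 and CR 7, and no fit left out both. Leaving out 1 array cannot show whether these calls rest on that pair. The NK list (0.24 to 0.40) was not called without CR 7 (0.27, adjusted p = 0.0536). The T cell list (0.22 to 0.38) was not called without control 4 (0.26), control 5 (0.22), control 6 (0.28), CR 2 (0.24), CR 6 (0.26) or CR 7 (0.29), with adjusted p from 0.0623 to 0.119. For the neutrophil list (-0.56 to -0.17) these arrays were control 1 (-0.38), control 2 (-0.25), control 4 (-0.37), CR 4 (-0.33), CR 6 (-0.23) and CR 7 (-0.17), with adjusted p from 0.0539 to 0.212. For the inflammatory list (-0.45 to -0.11) they were control 1 (-0.23), control 2 (-0.22), control 6 (-0.22), CR 5 (-0.27), CR 6 (-0.11) and CR 7 (-0.16), with adjusted p from 0.0541 to 0.291. For the insulin list (-0.18 to -0.099) they were control 2 (-0.15), control 4 (-0.12), control 5 (-0.11), CR 2 (-0.14), CR 6 (-0.12) and CR 7 (-0.099), with adjusted p from 0.0532 to 0.162. For the ribosomal list (0.12 to 0.26) they were control 1 (0.15), CR 2 (0.12) and CR 3 (0.15), with adjusted p from 0.0578 to 0.208. For the splicing list (-0.11 to -0.060) they were control 5 (-0.060, adjusted p = 0.12) and CR 7 (-0.082, adjusted p = 0.0539).

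The ribosomal list was also not called after quantile normalization (0.096), in the upper 25% (0.18), with array weights (0.12), with the mean of a gene's probe sets (0.12) and without control 1 and CR 2 (0.072). The oxidative phosphorylation list was not called without those arrays (0.080), nor the T cell list in the upper 25% (0.27) and with array weights (0.26). Calls also ended for the neutrophil list with a floor of 64 (-0.31) and the mean of probe sets (-0.34), the inflammatory list without the filter (-0.24) and the insulin list without a variance trend (-0.14). In 1 case a cell type score passed, NK without CR 5 (0.40), so that the count of cell type scores past the threshold ran from 0 to 1. Beyond the tests that changed and the arrays left out, the cause was not tested.

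Of the other lists, 7 were called somewhere. The mitochondrial ribosomal list (0.077 to 0.18 over the arrays left out) was called without control 2 (0.18), control 3 (0.15), control 6 (0.14), control 7 (0.13), CR 4 (0.14), CR 5 (0.14), CR 6 (0.14) or CR 7 (0.15), and with quantile normalization (0.13), median centring (0.16) and the mean of probe sets (0.13), besides the block (0.12). The interferon list (-0.23 to -0.029) was called without control 1 (-0.23), control 6 (-0.14), CR 1 (-0.17) or CR 6 (-0.18), with array weights (-0.22), with the mean of probe sets (-0.14) and without control 1 and CR 2 (-0.20). Complement receptors were called without control 1 (-0.34), control 7 (-0.30), CR 1 (-0.38), CR 4 (-0.29) or CR 5 (-0.29), without the filter (-0.29), with array weights (-0.29) and without control 1 and CR 2 (-0.41). Toll-like receptor genes were called without control 1 (-0.18) and without control 1 and CR 2 (-0.21), the cell cycle list without CR 2 (0.14), heat shock genes without control 2 (-0.11) and B cell markers without control 1 and CR 2 (0.29).

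Of 693 values of the other 25 lists, 597 kept sign and side, 32 in 7 lists passed the threshold and 64 in 16 lists had the other sign, mostly at differences near 0. Over the arrays left out, the values that crossed 0 ran from -0.084 to 0.14 for MHC class II, -0.0050 to 0.15 for the tricarboxylic acid cycle, -0.0039 to 0.16 for the proteasome, -0.057 to 0.055 for autophagy, -0.085 to 0.058 for the circadian clock, -0.052 to 0.071 for antioxidant targets. They ran from -0.32 to 0.21 for platelet, -0.13 to 0.028 for dendritic cell and -0.18 to 0.049 for plasma cell markers (list means and scores alike). They ran from -0.051 to 0.036 for sirtuins, -0.0060 to 0.12 for glycolysis, -0.38 to 0.012 for complement receptors, -0.13 to 0.0072 for the unfolded protein response, -0.095 to 0.10 for SIRT1 and -0.087 to 0.048 for TXNIP. Median centring gave 0.013 for TXNIP, 0.031 for antioxidant targets, 0.022 for sirtuins and 0.016 for the circadian clock. The upper 25% gave 0.061 for dendritic cells, -0.013 for MHC class II, 0.069 for sirtuins and 0.014 for the clock. Array weights gave -0.049 for SIRT1, -0.095 for MHC class II and -0.035 for autophagy. The mean of probe sets gave 0.026 for plasma cells, 0.0054 for heat shock and -0.046 for autophagy. Cell type covariates gave 0.049 for heat shock, 0.051 for the unfolded protein response, 0.13 for antioxidant targets, -0.026 for the cell cycle, 0.047 for toll-like receptors and 0.20 for complement receptors. Without control 1 and CR 2 the means were 0.011 for plasma cells (mean and score), -0.11 for MHC class II, -0.031 for the tricarboxylic acid cycle, -0.014 for glycolysis, -0.063 for the proteasome and -0.088 for autophagy. The cause of these crossings was not tested.

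Of 48 named genes with another tested probe set, 15 had one of the other sign: -0.21 for BECN1, 0.23 and 0.19 for CD55, -0.65 for CPT1A, 0.15 and 0.094 for HNRNPK, 0.19 for IL6, -0.047 for IRF3, -0.0010 for IRF7, 0.38 for IRS2, -0.067 for ITGB3, 0.023 for MED1, 0.16 for MPO, -0.27 for RPL15, -0.19 for RPL29, 0.080 for TCF7 and -0.094 for UQCRC1. The signal sets a limit as well, since the 50% of probe sets left out as dim were not tested in the reported fit, and 46 of 100 simulated changes of 1 log2 unit were recovered at this number of arrays. Those were planted among 200 changes, and the threshold is stricter where fewer probe sets change.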

Other observations

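The comparison of the immediate early list with the monocyte score, the comparison of the oxidative phosphorylation list after quantile normalization and the comparisons of the NK list with other lymphoid lists and of both the NK and immediate early lists with the platelet score were tests chosen after the result was seen, as was the search for on-or-off probe sets. The other tests in this part were set before their results.

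Within lists that were not called, the members below were among the 2 with the smallest p of their list, and none passed after adjustment over all probe sets (limma). In the list of sirtuins, AMPK and mitochondrial biogenesis, the nuclear sirtuin SIRT7 was at 0.43 ± 0.15 with 7 of 7 CR values above the control median and NAMPT at -0.65 ± 0.25 with 0 of 7 (smallest adjusted p over the list alone 0.0959). In the mitochondrial ribosome, MRPL41 was at 0.81 ± 0.26 and MRPS23 at -0.47 ± 0.17. In the glucocorticoid response list, ANXA1 (annexin A1) was at 0.36 ± 0.17 and SGK1 at -0.99 ± 0.49. Among glycolytic and cell cycle genes, PKM (pyruvate kinase) was at 0.52 ± 0.19 and MCM3, a subunit of the replicative helicase, at 0.47 ± 0.19. Among chaperones and folding enzymes, HSPA9 was at -0.50 ± 0.20 and PDIA6 at -0.41 ± 0.18, each with 0 of 7 CR values above the control median, and 2 proteasome subunits, PSMD8 (0.57 ± 0.28) and PSMC4 (0.57 ± 0.28), had 7 of 7 above.

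Other splits of the 14 arrays did not exclude chance for the count at unadjusted p or the count of called lists. Among 100 splits into 7 and 7, the diet split included, 36 gave at least 1350 probe sets at unadjusted p under 0.05 (highest other 4151), and 19 gave at least 10 called lists (highest other 18, median 5). The count of 0 at adjusted p under 0.05 is reached by any split (100 of 100, highest other 68), so for it the splits test nothing. Correlated genes and a structure among the arrays other than diet would both give splits with higher counts, and the 2 were not tested apart. With an estimated correlation, 0 lists were called in the diet split and in each other split, so that 0 does not set the diet split apart.

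For the higher signal of the NK and cytotoxic list in CR, a hypothesis is that fewer monocytes in the CR samples raised the share of lymphocyte RNA. With the monocyte score as a covariate the difference of the NK score was 0.19 ± 0.12 (SE) against 0.32 without it. The NK score minus the mean of the B cell and the naive and memory T cell scores was 0.28 ± 0.15 higher in CR (exact permutation p = 0.095, 7 of 7 CR arrays above the control median), so a part that is specific to cytotoxic cells and a part shared by lymphocytes cannot be told apart at this spread. That mean left out the T cell score, which was 0.30 higher in CR, close to the 0.32 of the NK score. The NK score was not compared with the T cell score. With the platelet score as a covariate the difference was 0.31 ± 0.14, which argues against platelets as its main source, and with the GAPDH and EF1A 3-prime to 5-prime ratios it was 0.30 ± 0.17, and the SE is too wide to exclude RNA quality as a source. An effect of the diet on cytotoxic cells, or of the age ranges of the groups, stays open and untested.

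The lower signal of immediate early genes in CR was also compared with cell shares. With the monocyte score as a covariate, the difference of the list score went from -0.36 to -0.17 ± 0.13 (SE), less than 0.5 of its size, which is consistent with a lower monocyte share in some CR samples as a source of part of it. With the platelet score, which correlated with the monocyte score at 0.663 over the 14 arrays, it was -0.33 ± 0.15. With the GAPDH and EF1A ratios as covariates it was -0.36 ± 0.21, too wide to exclude them. A smaller response of the cells to blood handling, or an effect of the diet, was not tested and stays open.

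For oxidative phosphorylation genes, the difference of the score was 0.17, and it was 0.18 ± 0.13 (SE) with the GAPDH and EF1A ratios as covariates and 0.16 ± 0.13 after quantile normalization, where camera still called the list. Neither moved the difference much, and the bar set for excluding either was not met. That bar uses the SE between animals, which does not measure how far re-scaling the same arrays moved the difference. The kept size (0.16 against 0.17) and the kept call argue against array scaling as the main source, while RNA quality stays open. The mean of the list without control 1 and CR 2 was 0.080, so the pattern may rest in part on those arrays. The diet remains an open explanation that these arrays do not test apart from chance.

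A search for probe sets with a gap of at least 4 log2 units between arrays and at least 3 arrays on each side found 5 of the 26383 tested. MBLAC2 was at 14.34 on 6 arrays (2 control, 4 CR) and 4.96 on 8, while its 3 other probe sets differed by 0.18 between the same arrays. LOC719654 was at 11.42 on 9 arrays (3 control, 6 CR) and 4.56 on 5, and its 3 other probe sets differed by 2.57. The other 3 probe sets have no gene listed, and each was on in 11 arrays (5 control, 6 CR). The smallest Fisher's exact p against diet was 0.266 (adjusted 1).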
